A study of Mus musculus with 8 samples.

How the data were processed

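Reduced representation bisulfite sequencing was done on 8 samples of sorted mouse muscle stem cells, 4 labelled as fixed and 4 as live, with 95 ng of DNA per library, 76 sequencing cycles and 20% PhiX control DNA, per the labels' protocols. The labels state 4 animals per group. The series title speaks of in situ fixation, while the design text places the fixation step after isolation. The libraries were made together as a pool, per the labels' protocols. The submitters' processing notes name Trim Galore 0.4, Bismark 0.14.4, ChIPseeker 1.12.1 and the mm10 build. The tool that called the regions, its coverage filter and its significance threshold are not given in the sources used here.

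The deposited data are a table of 21 differentially methylated regions and 2 lists of clusters, of 21 significant and 27857 not significant. The p-values in the authors' deposited table are those of its region p column; whether they were adjusted is not given in the sources used here. The authors' deposited table also holds a signed median methylation difference between its groups, given as a fraction and reported here in percentage points, and the distance in bp to the start of the assigned transcript. A further 2 columns hold a median level for each group under the names group 1 and group 2. These names match neither fixed nor live in the labels, so the 2 columns were not used. They had been read when the units were checked and in a first version of the scripts, and every result drawn from them was removed. The called clusters and the table hold identical coordinates for all 21 regions, no cluster is in both lists, and neighbouring clusters lie at least 100 bp apart. No value per sample or read depth is given for any cluster in the files used here, so no test across animals was run and the precision of each difference is unknown.

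The following was computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only; where 0 clusters were called, the limit is 3 clusters of the total. Clusters near each other are not independent, so p-values over clusters describe these lists and not the animals. The sign of the differences was tested with an exact two-sided binomial test, positions, chromosomes and gene lists with two-sided Fisher's exact tests, and lengths with 100000 random draws of 21 clusters. The share of list genes with a cluster was tested on the protein-coding genes of each list against all other protein-coding genes; a first version had counted noncoding imprinted genes among them and was corrected. Benjamini-Hochberg adjustment was applied over chromosomes, over lists and over the class tests.

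Gene positions came from RefSeq genes of GRCm38.p6, the assembly that mm10 names. That table gives no strand, so the planned promoter test around start sites was replaced by windows around both gene ends, gene body shares excluded both ends, and gene list windows ran 3000 bp beyond both ends of each gene. The promoter class is the one in the authors' deposited table. The planned test of CpG density, GC content and repeats needs a genome sequence and was not run. The choice of tests, the 14 gene lists (265 genes, 264 found by symbol) and the rule for naming genes were fixed before the data were examined. By that rule the text names the gene of every called region, any list gene with a called cluster and the first 3 genes of each list that hold a cluster. Some called regions and list genes covered by this rule are left out of the text, and counts include them. Genes that host a region without being the assigned gene were named after their positions were seen.

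Of the tests, only Fisher's exact test for chromosome X and the length test, with fewer random draws than above, were tried on simulated data. In 200 random draws of 21 clusters with no planted effect, 1.5% were called by Fisher's exact test for chromosome X and 7.5% by the length test at p under 0.05. With 6 of 21 regions planted on chromosome X, or 16 of 21 among the longest clusters, 100% of 200 draws were called. These planted effects were large, and how often smaller ones would be called was not tested. The alternatives covered stricter differences and p, merging and minimum length, window size, overlap, protein-coding genes only, autosomes only and another gene window.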

Results

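DNA methylation was measured by reduced representation bisulfite sequencing, which reads the methylation of cytosines in a CpG-rich fraction of the genome, in muscle stem cells of mice carrying a nuclear GFP reporter of Pax7, the transcription factor that marks these cells. The design text contrasts cells fixed with 0.5% paraformaldehyde and cells that were kept live, with 4 samples and 4 stated animals in each group. The question was whether fixation alters DNA methylation levels. The series title and the design text differ on when cells were fixed, so an effect of fixation may not be separable from one of handling. The deposited lists hold 27878 clusters of neighbouring sites, covering 3257029 bp on 22 chromosomes, the mitochondrial genome included, with the authors' verdict on each cluster. Values per sample and read depth were not used here, so the spread between animals is unknown. Each called region has a signed median methylation difference in the authors' deposited table. The sources used here do not state which group was subtracted from which, so the text gives the sign and does not assign a direction to fixation.

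Few regions were called different. In the authors' lists, 21 of 27878 clusters were significant, a share of 0.0753% with an exact Clopper-Pearson 95% interval of 0.0466 to 0.115% that covers counting error only. The called regions together spanned 1959 bp, or 0.0601% of the length covered, and lay on 14 chromosomes. Across the 21 regions, the absolute methylation difference in the authors' deposited table had a median of 18.4 percentage points and ranged from 10.8 points at Capn9, which encodes a calpain protease, to 61.6 points at a single position assigned to Tff3, which encodes a trefoil peptide. The next largest difference was 34.2 points, at Det1. The largest p in the authors' deposited table was 1.50e-05, and 1 region was listed with a p of 0. The table's own numbers skip values. Counted chromosome by chromosome, 73 clusters at the head of the list of not significant clusters could take the missing places.

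The annotation in the authors' deposited table placed 6 of the 21 regions in promoters, 5 in introns, 4 in exons and 6 in distal intergenic sequence. Of the promoter regions, 3 lay within 1 kb of a transcript start and 3 lay 2 to 3 kb away, and 4 of the 6 had a negative difference. Among those within 1 kb, the region at Ece1 (chromosome 4, 137920758 to 137920889, mm10), which encodes endothelin converting enzyme 1, had a difference of -21.7 percentage points in the authors' deposited table. The region at Pls3 (chromosome X, 75874084 to 75874217), which encodes the actin-bundling protein plastin 3, had the opposite sign, with 18.4 points in the same authors' deposited table. At 1700030C10Rik (chromosome 12, 20815327 to 20815515), the authors' deposited table gave -18.3 points. Of the more distant promoter regions, at Det1 (chromosome 7, 78844181 to 78844223), which encodes a ubiquitin ligase component, the authors' deposited table listed 34.2 points, the largest positive difference. The region assigned to Mir1188, a microRNA gene, lay inside the imprinted noncoding RNA gene Rian (chromosome 12, 109614563 to 109614706) and had -16.8 points in the authors' deposited table.

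All 5 intronic regions had a negative difference in the authors' deposited table, as did 3 of the 4 exonic regions. The single position on chromosome 17 (31095763) had -61.6 points in the authors' deposited table. It was assigned to Tff3, whose transcript start lies 33848 bp away, but lay in intron 4 of Abcg1, which encodes a cholesterol transporter. In the last intron of Arhgap44 (chromosome 11, 65126779 to 65126825), a GTPase-activating protein gene, the authors' deposited table gave -23.3 points. The intronic regions of Fam105a (RefSeq name Otulinl; chromosome 15, 27666832 to 27666845), of the cell polarity gene Pard6g (chromosome 18, 80073427 to 80073485) and of Capn9 (chromosome 8, 124617510 to 124617604) had -23.0, -15.9 and -10.8 points in the authors' deposited table. Of the exonic regions, the one in the last exon of Sema6c (chromosome 3, 95172835 to 95172902), a semaphorin gene, had -25.7 points in the authors' deposited table. The exonic region of Fbrsl1 (chromosome 5, 110378176 to 110378250) had -13.1 points in the authors' deposited table. The exonic region assigned to the chromatin regulator gene Kansl1, lay in exon 9 of Mapt, which encodes the microtubule protein tau (chromosome 11, 104318117 to 104318237), with 14.5 points in the authors' deposited table.

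The 6 distal intergenic regions were split evenly, with 3 negative and 3 positive differences in the authors' deposited table. Those with a negative difference were assigned to Slc16a9 (chromosome 10, 70291552 to 70291772), a monocarboxylate transporter gene, to Zfp326 (chromosome 5, 106163904 to 106164045), a zinc finger gene whose transcript start lies 287336 bp away, and to Frg1 (chromosome 8, 41552084 to 41552177), with differences of -22.1, -23.5 and -17.0 points in the authors' deposited table. Those with a positive difference were assigned to Gm13212 (chromosome 4, 145632623 to 145632692), to the prolactin family gene Prl5a1 (chromosome 13, 28165089 to 28165171) and to the procollagen processing gene Pcolce2 (chromosome 9, 95605405 to 95605469), with differences of 30.2, 27.8 and 18.1 points in the authors' deposited table. In RefSeq annotation, the region assigned to Gm13212 overlapped the pseudogene Gm13234 and the region assigned to Slc16a9 overlapped the noncoding RNA gene Gm40687.

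**Figure D1:**
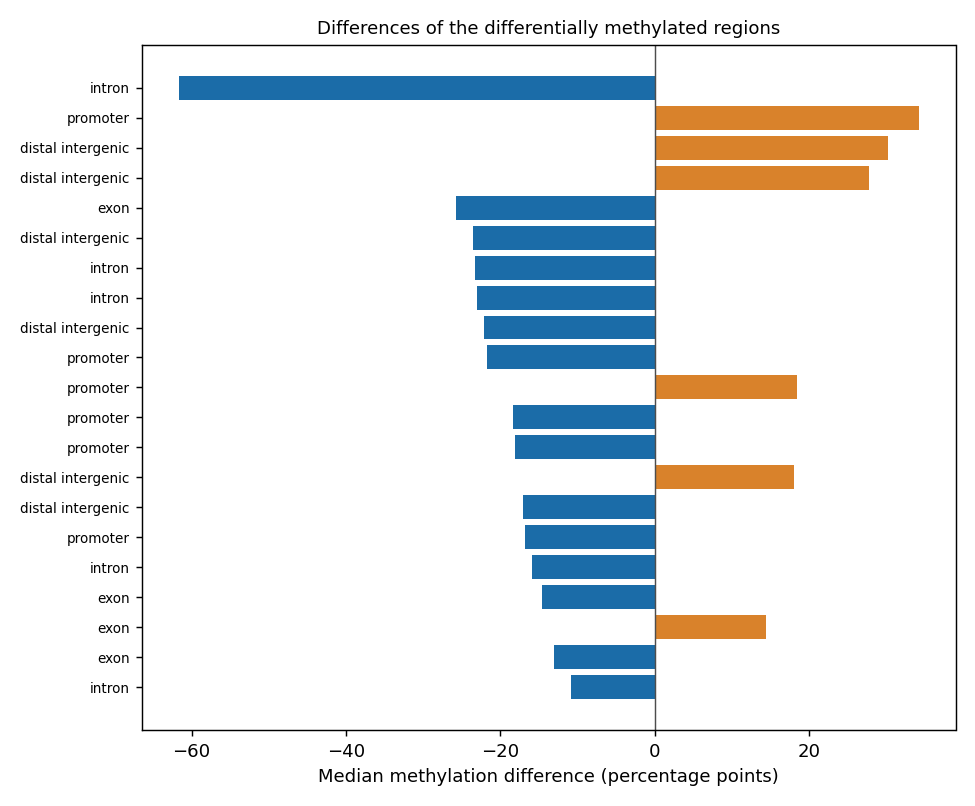
Median methylation difference in percentage points (horizontal axis) for each of the 21 called regions, one bar per region, ordered by the size of the difference, as given in the authors' deposited table; blue bars are negative and orange bars positive, and the labels give the annotation class. The single position assigned to Tff3 stands apart at -61.6 points, and 15 of the 21 bars are negative.

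In all, 15 regions had a negative and 6 a positive difference in the authors' deposited table. The negative share was 71.4% (exact 95% interval 47.8 to 88.7%), which was not shown to differ from equal shares in an exact two-sided binomial test (p = 0.0784).

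Compared with the clusters that were not called, the called regions were not shown to differ in their position relative to genes with windows of 3000 bp. Within 3000 bp of either end of a RefSeq gene lay 42.9% of the called regions (exact 95% interval 21.8 to 66.0%) and 49.7% of the others (two-sided Fisher's exact test, p = 0.664). Inside a gene and farther than that from any gene end lay 38.1% of the called regions (18.1 to 61.6%) and 29.6% of the others (Fisher's exact test, p = 0.473). Outside genes and these windows lay 4 of the 21 called regions and 20.7% of the others (Fisher's exact test, p = 1). With protein-coding genes only, 23.8% of the called regions and 39.6% of the others lay within 3000 bp of a gene end (Fisher's exact test, p = 0.181), and 38.1% against 30.4% lay outside genes and windows (Fisher's exact test, p = 0.478). With windows of 1000 bp, 9.52% of the called regions and 33.0% of the others lay near a gene end (Fisher's exact test, p = 0.0200), and 71.4% against 42.8% lay inside a gene away from any gene end (Fisher's exact test, p = 0.0132). Neither passed adjustment over the 12 Fisher's exact tests of position (Benjamini-Hochberg p = 0.120 for both), and 3 called regions lay just outside that window, at 1032 bp (Pls3), 1174 bp (Capn9) and 1182 bp (Sema6c) from a gene end. Gene ends here are the outer bounds of each gene, so transcript starts inside a gene do not count. The Ece1 and Pls3 regions, in promoters within 1 kb of a transcript start in the authors' deposited table, therefore count as away from gene ends with the 1000 bp window.

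**Figure D2:**
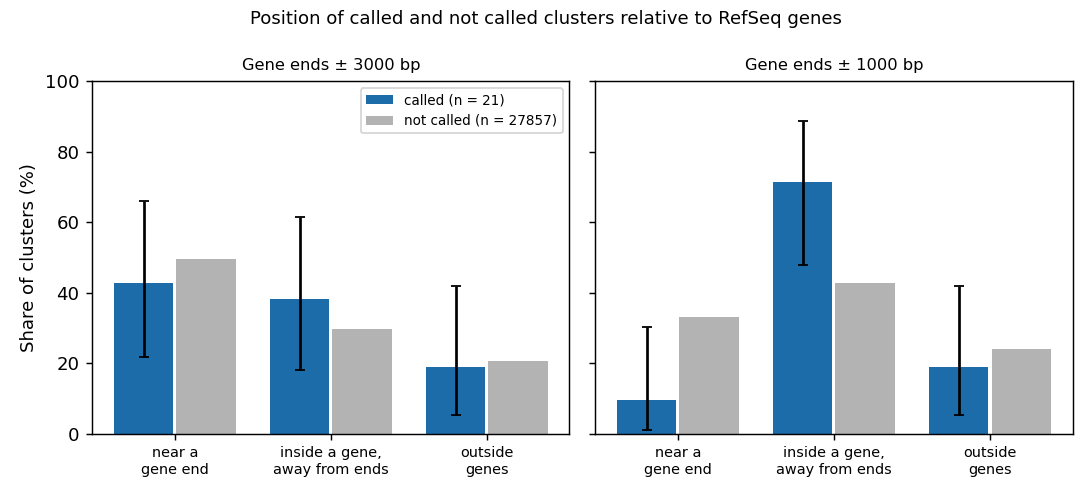
Share of clusters in percent (vertical axis, from 0) that lay near a RefSeq gene end, inside a gene away from any gene end, or outside both, for the 21 called regions (dark bars, with exact 95% intervals as error bars) and the 27857 others (grey bars), with windows of 3000 bp (left) and 1000 bp (right). The near-end share of called regions is 42.9% on the left and 9.52% on the right.

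With 21 called regions, no chromosome was shown to hold more or fewer of them than its share of the listed clusters. Chromosome 4 had 3 called among 2009 clusters and chromosome X had 2 among 1133, and the smallest p over 22 two-sided Fisher's exact tests was 0.190, for chromosome 4 (0 chromosomes under an unadjusted p of 0.05, all Benjamini-Hochberg p = 1). In a set chosen after the data were seen, the 73 clusters at the head of the other list were added, although the authors list them as not significant. Chromosome 4 then held 17 of 94 (Fisher's exact test, Benjamini-Hochberg p = 0.00801). The lists also hold 14 clusters on chromosome Y and 6 on the mitochondrial genome, with 0 called in either. The called regions had a median length of 83 bp and the others 89 bp (permutation test with 100000 resamples, two-sided, p = 0.785).

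No cluster was called at the genes that define muscle stem cells and their early response, although part of these genes held no cluster and so could not be called. At the overall called share of 0.0753%, only 0.0407 calls were expected for the identity and quiescence list. For the immediate early and stress response list 0.0347 were expected. Counts of 0 therefore cannot show that these genes were spared. Of 264 list genes found in the annotation, 193 had at least 1 cluster within 3000 bp of the gene, 490 clusters in all, and 1 of these was called. The muscle stem cell identity and quiescence list held 54 clusters at 13 of its 20 genes, among them 20 at Pax7, 4 at Pax3 and 1 at Calcr, the calcitonin receptor gene, with 0 called, which allows a called share of up to 5.56%. The immediate early and stress response list held 46 clusters at 22 of its 27 genes, with 1 at Fos, 4 at Fosb and 2 at Fosl1, components of the AP-1 transcription factor, and 0 called, which allows up to 6.52%. The myogenic commitment and differentiation list held 30 clusters at 12 of its 20 genes, with 1 at Mef2a, 2 at Mef2c and 2 at Mef2d, transcription factors of muscle differentiation, and 0 called. The Notch pathway list held 36 clusters at 17 of its 18 genes, with 1 at Notch1, 2 at Notch2 and 4 at Notch3, receptors of the pathway, and 0 called. The cell cycle list held 21 clusters at 12 of its 19 genes, with 1 at Ccnd1, 2 at Ccnd2 and 5 at Ccnd3, D-type cyclins, and 0 called.

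Among the imprinted genes, 1 of 82 clusters was called, the only cluster at Rian, against 0.0618 expected from the overall share (two-sided Fisher's exact test, p = 0.0600, Benjamini-Hochberg p = 0.840 over 14 lists). The clusters at H19 (3), Igf2 (7) and Peg3 (1), imprinted genes whose methylation differs between parental alleles, were not called. The list of DNA methylation enzymes and readers held 30 clusters, with 5 at the maintenance methyltransferase gene Dnmt1, 3 at Dnmt3a and 1 at Dnmt3b, and 0 called. The Hox genes, transcription factors of body patterning, held 133 clusters, among them 3 at Hoxa2 and 11 at Hoxa3, and 0 called, which allows up to 2.26%.

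No cluster was called at the markers of other cell types that a sort could carry over. The endothelial markers held 23 clusters, including 3 at Pecam1, 3 at Kdr and 1 at Vwf. The haematopoietic markers held 3 clusters, among them 1 at Ptprc and 1 at Itgam. The fibro-adipogenic progenitor markers held 6, with 2 at Pdgfra, 1 at Col1a1 and 2 at Cd248; the smooth muscle and pericyte markers held 9, with 1 each at Pdgfrb, Acta2 and Cspg4. The Schwann cell markers held 14, among them 3 at Sox10 and 4 at Mbp, and the mature myofibre markers held 19, with 3 at Acta1, 1 at Myh2 and 3 at Ckm. For all 14 lists the expected number of called clusters was under 1, so these counts cannot show that a list was called less often than others.

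**Figure D3:**
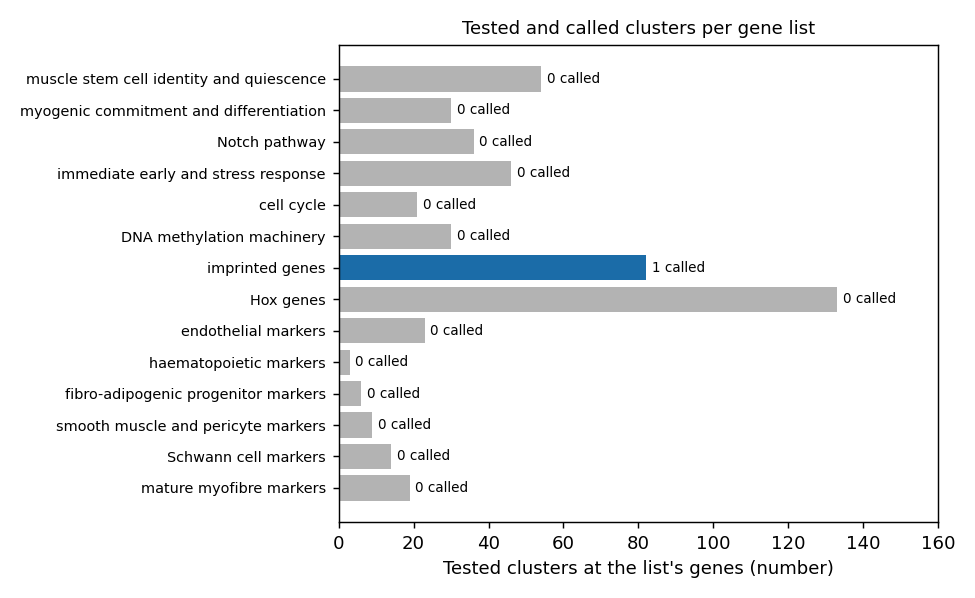
Number of clusters in the authors' lists at the genes of each gene list (horizontal axis), with the number called written beside each bar; the dark bar marks the list with a called cluster. Coverage ran from 3 clusters at haematopoietic markers to 133 at Hox genes, and the single called cluster lay at Rian among the imprinted genes.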

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

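The choices named here as added were made after the data were examined. A difference of at least 0.1, matching of the table to the list by 1 bp or 50% reciprocal overlap, and merging of neighbours within 1000 bp kept the same 21 regions, so these alternatives tested nothing. The count was 17 with a length of at least 50 bp. It fell to 10 with a difference of at least 0.2 and to 12 with a p 10 times smaller than the largest, both by removing regions, and was 94 with the 73 clusters at the head of the other list included (added). The lean to negative differences was tested in 2 of the alternatives that changed the set of regions, and stayed short of the threshold in both (7 of 10 regions with a difference of at least 0.2, binomial p = 0.344, and 12 of 17 with a length of at least 50 bp, p = 0.143, both added). It was not tested in the 12 regions with the smaller p, where only those assigned to Pls3 and Kansl1 had a positive difference. That split was more uneven than in the 2 alternatives tested, so the lean may pass the threshold there. The 1000 bp window moved the near-end share to 9.52% (added, Fisher's exact test, p = 0.0200) and the gene body share to 71.4% (Fisher's exact test, p = 0.0132), past the unadjusted threshold; the cause was not tested. Windows around gene ends only (added) left 0 called clusters at list genes, since the Rian region lies away from the gene's ends. With protein-coding genes only the near-end share fell to 23.8% (Fisher's exact test, p = 0.181, added). With the 94 regions (added), 1 chromosome, chromosome 4, passed the adjusted threshold (Fisher's exact test, Benjamini-Hochberg p = 0.00801), against 0 with the 21. The other alternatives that were run changed no side of a threshold. No paired analysis was possible because the files used here hold no value per sample, although the labels share the letters a to d; for the same reason no replicate could be left out. Start-site windows, the promoter share with protein-coding genes or overlap, and the sequence content test with its wider window were not run. The unknown read depth limits what the clusters that were not called can show.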

Other observations

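All tests in this part were chosen after the data were seen. The clusters covered some gene groups far more than others. Of 21896 protein-coding genes, 47.9% had a cluster within 3000 bp of the gene, against 38 of 39 Hox genes (97.4%, two-sided Fisher's exact test, Benjamini-Hochberg p = 3.22e-10 over 14 lists), 17 of 18 Notch pathway genes (94.4%, adjusted p = 0.000204), 29 of 35 protein-coding imprinted genes (82.9%, adjusted p = 0.000182), 22 of 27 immediate early and stress response genes (81.5%, adjusted p = 0.00143) and 15 of 18 genes of the DNA methylation machinery (83.3%, adjusted p = 0.00942). Neighbouring genes, such as Hox genes, can share a cluster, so the genes counted in these Fisher's exact tests are not independent. For the other 9 lists the adjusted p was 0.116 or more, with 3 of 14 haematopoietic markers (21.4%) and 13 of 20 genes of muscle stem cell identity and quiescence (65.0%) covered. Myod1 and Myf5, regulators of the myogenic lineage named here after the results were seen, had 0 clusters.

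The region table's own numbers run from 8 to 93 over 21 regions. The list of not significant clusters opens with 73 clusters that stand before its part ordered by chromosome. When these clusters and the 21 regions were counted together, chromosome by chromosome, all 21 numbers fell in the places their chromosome left for them, while 0 of 10000 random sorted numberings did so and the best of them placed 17. The 73 clusters may therefore be regions that passed a first step and were dropped at a second, giving 94 regions or 0.337% of clusters. The smallest difference in the authors' deposited table, 10.8 points, would go with a size limit near 10 points, but the 73 clusters carry no values, so what set them apart was not tested.

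Of the 94 regions, 17 (18.1%) lay on chromosome 4, which held 7.21% of the clusters (two-sided Fisher's exact test, Benjamini-Hochberg p = 0.00801 over 22 chromosomes). The share exceeded that of the clusters, but how the 73 clusters were selected is unknown. Of the 17 regions, 14 came from the 73 clusters, of which they made up 19.2%. Of the 21 called regions, 3 lay on chromosome 4. Counting each 1 Mb bin once left 13 of 84 bins with a region on chromosome 4 (15.5%, against 6.04% of all bins, Fisher's exact test, p = 0.00126). The bin test was run for chromosome 4 only, after its share was seen, and its p is unadjusted. Chromosome 4 also carries Pax7 (139737059 to 139833530), the gene the reporter transgene is named for. A segment linked to Pax7 that differed between animals was a candidate explanation. The regions lay a median of 14.2 Mb from Pax7 and the other clusters of that chromosome 14.6 Mb (permutation test, p = 0.897). Where the transgene lies was not established here, so distance to Pax7 need not measure linkage to it. Linkage is neither shown nor excluded. At a cut set after the positions were seen, and so not used as a test, 16 of the 17 regions and 70.2% of the other clusters lay beyond 100 Mb. No values are given for the 73 clusters, so a biological difference between fixed and live cells there was not tested.

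The names of the called clusters carry a running number per chromosome. At the 19 autosomal regions, the rank among the listed clusters was 50.3 to 65.5% of that number, and at the Pls3 region on chromosome X it was 91.5%. What the unlisted numbers stand for is unknown. The called shares and the chromosome tests above therefore refer to the listed clusters only.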
